A study of Mus musculus with 12 samples.

How the data were processed

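Quadriceps muscle of C57Bl/6J mice was profiled on 12 Affymetrix mouse expression arrays, 3 for each of 4 groups: vehicle, AICAR, GW1516 and the combination. Per the labels, treatment lasted 6 days, doses were 250 mg/kg/day for AICAR and 5 mg/kg/day for GW1516, and RNA of 3 mice was pooled for each array. The deposited intensity values are MAS5 signals, per the submitters' processing notes, on a linear scale with 1 value per probe set. Each array had been scaled to a trimmed mean of 200, as checked on the values. The MAS5 version, the scanner settings and the genome build are not given in the sources used here, and detection calls were not used here. Probe sets were named from an array annotation dated 2016, and 34754 were matched to a gene table by gene ID, which changed 0 symbols. No coordinates are given.

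Of 45101 probe sets, 64 controls were left out. Of the other 45037, 34945 carried 1 gene symbol, 932 carried several and 9160 were unnamed here. Signals below 1 were set to 1 (3531 of 540444 values) and log2 was taken, with no further normalization between arrays. Probe sets in the lowest 40% by mean log2 signal, below a signal of 28.2, were left out, which kept 27022 and, with 1 symbol, 22714. Each gene was represented by its brightest probe set, giving 12771 genes, of which 5781 had more than 1 probe set past the filter. Cpt1b and Myh7 were to be named whatever their result, but were not among the genes tested.

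Groups were compared with limma 3.58.1 in R 4.3.3, with a mean per group, moderated variances with a trend on mean signal, 8 residual and 5.91 prior degrees of freedom, and all 12 arrays in the fit. The 7 contrasts were each drug and the combination against vehicle, the 3 direct comparisons, and the interaction, which is the combination minus AICAR minus GW1516 plus vehicle. Tests were two-sided, p-values were adjusted over all genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p below 0.05. A moderated F test compared the 4 groups. Correlations of log2 changes between comparisons that share the vehicle arrays are given beside 100 simulations of unchanged groups.

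Gene lists for lipid and energy metabolism, muscle fibre types, atrophy, stress responses, the clock and other cell types, 27 in all, were tested with camera at a preset correlation of 0.01. The 26 with at least 5 measured members entered, and the red blood cell list did not. Some lists share members, so their results are not independent. Mlycd and Slc25a20 are in the PPAR target and fatty acid oxidation lists, and Pdk4 is in the PPAR target and atrophy lists. Camera with an estimated correlation per list and fry (statmod 1.5.0) were alternatives. Genes to name were set by rule: up to 8 per direction with the largest called change and no overlap between groups for comparisons with vehicle, 5 per direction for the others, genes of smallest p where fewer were called, a fixed set of PPAR, AMPK and fibre genes, and up to 4 members of each list called. The groups, comparisons, tests, lists, naming rule and alternatives were set before the data were examined, except the adipocyte marker score and the tests on GW1516 replicate 2 and on fat cells, which were chosen after seeing the data.

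Alternatives were quantile normalization, median centring, a pseudocount of 32, no filter, a filter of 60%, the mean of a gene's probe sets, all probe sets, variances without trend or with robust estimation, only the groups compared, other thresholds, array weights, the replicate number as a term, and each array left out in turn. The code was tested on simulated data for the combination against vehicle, with 200 changed genes in each of 20 simulations. It recovered 24.8% of genes changed by 0.5 on the log2 scale, 63.6% at 1, 77.3% at 1.5 and 87.7% at 2. Of its calls 5.66% were false, and 0 simulations without changes gave a call. A list shifted by 0.3 was found in 20 of 20 simulations, with a mean of 0.5 other lists called in each. Genes in these simulations were drawn independently, so camera was not tested where the members of a list move together. In the real data the estimated correlation was 0.83 for adipocyte markers. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.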

Results

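Gene expression was measured in quadriceps muscle of C57Bl/6J mice after 6 days of treatment with vehicle, AICAR at 250 mg/kg/day, GW1516 at 5 mg/kg/day or both drugs together. AICAR is an adenosine analogue that activates the AMP-activated protein kinase, a sensor of cellular energy, and GW1516 is a synthetic agonist of the nuclear receptor PPARδ, which drives genes of fatty acid use. Each of the 12 arrays was hybridised with RNA pooled from 3 mice, with 3 arrays in each of the 4 groups. The labels do not say whether the pools of a group shared mice, so p-values measure the spread between these pools. Every array had the same trimmed mean signal of 200, and the median signal ranged from 45.4 to 54.2. The ratio of 3' to 5' signal of the control probe sets, a measure of RNA integrity, was 0.802 to 0.880 for Gapdh and 0.782 to 0.936 for Actb. Correlations between arrays over the 12771 genes tested lay between 0.947 and 0.968. The second GW1516 array stood apart on the first principal component, with a score of 0.81, and this component held 13.4% of the variance. The number of arrays limits the precision: the median standard error of a difference between 2 groups was 0.19 on the log2 scale.

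Across the 4 groups, 14 genes differed by limma's moderated F test at an adjusted p under 0.05. They were Acadl, Col22a1, Dkk3, Eci2, Fbp2, Foxo1, Mlycd, Pfkfb3, Plin4, Ptp4a3, Rpl22l1, Slc25a20, Sult1a1 and Ucp3. Acadl, Eci2, Mlycd and Slc25a20 belong to mitochondrial fatty acid oxidation, Ucp3 is a mitochondrial uncoupling protein, Plin4 coats lipid droplets, and Pfkfb3 and Fbp2 act on glycolysis and gluconeogenesis. At an unadjusted p under 0.05 the F test gave 1333 genes, where 639 would fall by chance. Without the empirical Bayes trend the count was 0, and with array weights it was 45. It was 38 and 35 without GW1516 replicates 1 and 2, 9 and 7 without vehicle replicates 1 and 2, 7 without AICAR replicate 2 and 9 without combination replicate 2.

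**Figure D1:**
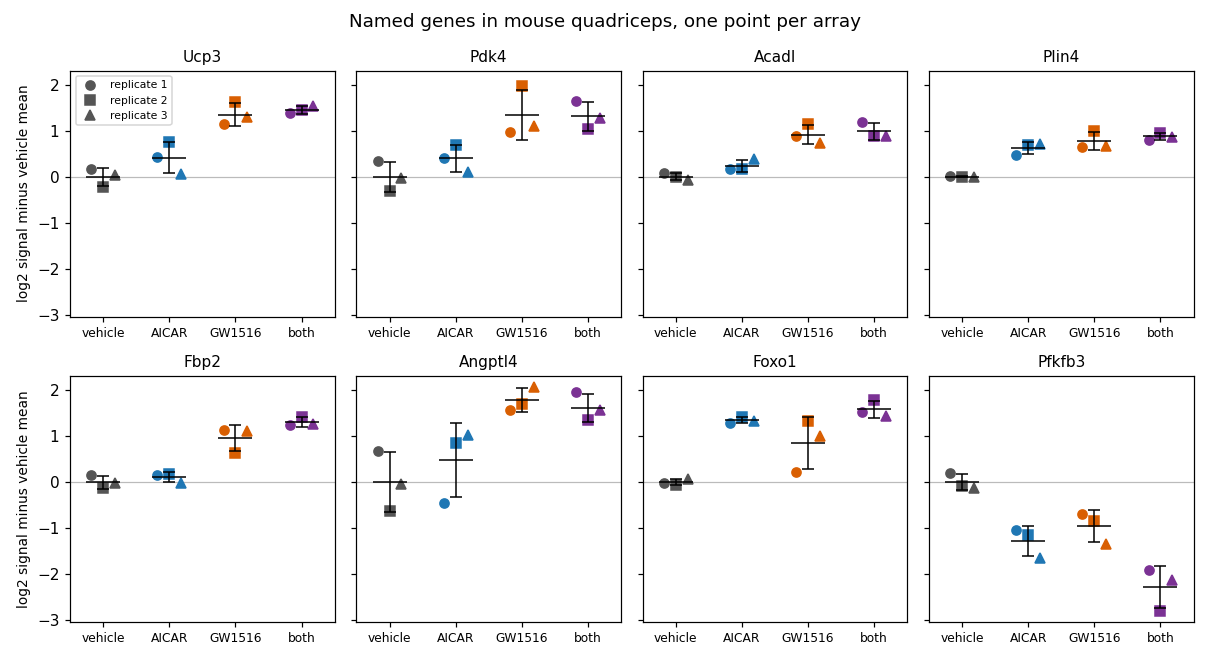
Each panel plots 1 gene as the log2 signal of an array minus the mean of the vehicle arrays, where points are arrays with the shape giving the replicate, and the black bar and whiskers are the mean and SD of 3 arrays. Ucp3, Acadl and Fbp2 lie above all vehicle arrays in both groups given GW1516, Foxo1 lies 1.35 above the vehicle mean with AICAR, and Pfkfb3 lies 2.28 below it with both drugs.

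The first comparison asked what AICAR alone did to muscle transcripts. Rpl22l1, a paralogue of a ribosomal protein gene, fell by 0.63 ± 0.072 (SE, n = 3 against 3 arrays) on the log2 scale, with all 3 AICAR arrays below the 3 vehicle arrays (limma, adjusted p = 0.00658). Some genes stood just outside the threshold. Foxo1, a transcription factor of fasting and atrophy, differed by 1.35 ± 0.20 (adjusted p = 0.0561), Plin4 by 0.63 ± 0.097 (adjusted p = 0.0561) and the sulfotransferase gene Sult1a1 by 1.01 ± 0.16 (adjusted p = 0.0563). Farther from the threshold, Pfkfb3, whose enzyme makes an activator of glycolysis, differed by -1.28 ± 0.22 (adjusted p = 0.129).

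Rpl22l1 was the 1 gene called of 12771 (0 higher, 1 lower), and 885 genes had an unadjusted p under 0.05, where 639 would fall by chance. Next in rank, none passing, were Adgrf5 at 0.57 and Ramp2 at 0.63, and on the lower side Cited4 at -0.79, Lppos at -0.70 and Pnmt at -1.21, all at an adjusted p of 0.164 by limma. Of the genes named beforehand, Pdk4 differed by 0.41, Angptl4 by 0.47, Ucp3 by 0.42, Fasn by 0.95, Scd1 by 0.76, Ppargc1a by 0.21, Myh4 by 0.13, Ppard by 0.01 and Prkaa2 by -0.03, none past the threshold. Without AICAR replicate 3 Fasn stood at 0.46 and Scd1 at 0.45, without AICAR replicate 2 Pdk4 stood at 0.26 and Ucp3 at 0.25, and Angptl4 ranged from 0.16 to 0.93 over the omissions of 1 array. The count was 0 without AICAR replicate 2, without AICAR replicate 3 or without vehicle replicate 2, and 8 and 6 without GW1516 replicates 2 and 1, which enter only through the shared spread. It was 2 without AICAR replicate 1 or vehicle replicate 1 and 3 without vehicle replicate 3. The count was also 0 without the trend, 28 when only AICAR and vehicle arrays were fitted, and 15 with array weights.

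Of 26 gene lists tested with camera at a preset correlation of 0.01, 6 passed for AICAR. Adipocyte markers were higher, with all 16 measured members above 0 and a median of 0.88 (adjusted p = 0.000532). With an estimated correlation the adjusted p = 0.803 for that list. Pparg stood at 1.45. These markers varied between arrays of a group: the list's median against the vehicle mean was -0.10, 0.94 and 1.66 in the AICAR arrays and 0.53, -0.40 and -0.16 in the vehicle arrays. The lipid uptake and storage list had a median of 0.28 with 15 of 17 members above 0 (camera, adjusted p = 0.00207, or adjusted p = 0.775 with an estimated correlation). The lipid synthesis list had a median of 0.32 with 15 of 18 above 0 (camera, adjusted p = 0.019, or adjusted p = 0.803 with an estimated correlation), as in Lpin1 at 0.38. Without AICAR replicate 3 these 3 lists lost the threshold, at medians of 0.40, 0.19 and 0.21 (camera, adjusted p = 0.174, 0.21 and 0.306), and lipid synthesis lost it in 4 of 12 omissions of 1 array.

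On the lower side for AICAR, 22 of 25 cytosolic ribosomal protein genes lay below 0, with a median of -0.10 (camera, adjusted p = 0.00102, or adjusted p = 0.599 with an estimated correlation). Rpl8 stood at -0.22 and Rps24 at -0.20, though 3 of the 6 probe sets of Rps24 went the other way, up to 0.41. Oxidative phosphorylation genes had a median of -0.06 with 51 of 61 below 0 (camera, adjusted p = 0.00722, or adjusted p = 0.906 with an estimated correlation), as in Cyc1 at -0.17. Immediate early and heat shock genes had a median of -0.19 with 15 of 20 below 0 (camera, adjusted p = 0.00838, or adjusted p = 0.599 with an estimated correlation), as in Dnajb1 at -0.39. This list lost the threshold in 2 of 12 omissions, and oxidative phosphorylation did with quantile normalization (median -0.03, camera, adjusted p = 0.215). None of these 6 lists held a member called over all genes, and adjusted over the list alone only Lpin1, in lipid synthesis, passed. With fry 0 lists passed, and another grouping of the same 6 arrays put 7 lists past the threshold.

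The second comparison asked what PPARδ activation by GW1516 did. Ucp3, a mitochondrial uncoupling protein, rose by 1.35 ± 0.16 on the log2 scale (2.55-fold, n = 3 against 3 arrays), Mlycd, whose enzyme removes malonyl-CoA, by 1.17 ± 0.18, and Acadl, the long-chain acyl-CoA dehydrogenase, by 0.92 ± 0.11, with limma's adjusted p = 0.00583, 0.0267 and 0.00583. Fbp2, muscle fructose bisphosphatase, rose by 0.96 ± 0.13 (adjusted p = 0.00779) and the lipid droplet gene Plin4 by 0.78 ± 0.097 (adjusted p = 0.00583). Col22a1, a collagen of tissue junctions, fell by 0.93 ± 0.13 (adjusted p = 0.0141), and Dkk3, a secreted Dickkopf family member, fell by 0.92 ± 0.15 (adjusted p = 0.0294).

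Of 12 genes called, 10 rose and 2 fell, and 1231 genes had an unadjusted p under 0.05, where 639 would fall by chance. The remaining 5 that rose were Exosc5 by 0.68, Eci2 by 0.60, Ptp4a3 by 0.60, Lpin1 by 0.58 and Tacc2 by 0.53. With 1 array left out in turn, Ucp3, Acadl, Fbp2, Plin4 and Col22a1 were called in 10 of 12 fits. Lpin1 was called in 9, Exosc5 in 8, Mlycd and Ptp4a3 in 6, Dkk3 in 4 and Eci2 in 2. Not past the threshold on the lower side were Tiam1 at -1.04 (limma, adjusted p = 0.0744), Nptn at -0.52 (adjusted p = 0.073) and Polh at -0.73 (adjusted p = 0.136). Among the genes named beforehand, Pdk4, a kinase that shuts pyruvate dehydrogenase, differed by 1.35 ± 0.24 and missed the threshold (adjusted p = 0.0712), as did Angptl4, a secreted inhibitor of lipoprotein lipase, at 1.78 ± 0.36 (adjusted p = 0.136). Fasn at 0.60, Scd1 at 0.12, Ppard at 0.38, Ppargc1a at 0.07, Prkaa2 at 0.26 and Myh4 at 0.19 did not pass either, and without GW1516 replicate 2 these 6 stood at 1.25, 0.90, 0.21, 0.04, 0.12 and 0.26, none of them passing. A second probe set of Col22a1 stood at 0.09, against -0.93 for the brightest. The calls leaned on the vehicle arrays, since 0 genes were called without vehicle replicate 2, 0 without vehicle replicate 3 and 6 without vehicle replicate 1, while 41 were called without GW1516 replicate 1. The count was 7 without AICAR replicate 2 or without combination replicate 2 or 3, 7 with the mean of a gene's probe sets, 2 when only GW1516 and vehicle arrays were fitted, and 0 without the trend.

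For GW1516, 11 lists passed camera, 8 higher and 3 lower. PPAR target genes had a median of 0.41 with 21 of 23 members above 0 (camera, adjusted p = 1.4e-11, or adjusted p = 0.343 with an estimated correlation). Over all genes 3 members were called, and 12 when adjusted over the list alone, among them Slc25a20 at 0.56. Mitochondrial fatty acid oxidation had a median of 0.15 with 18 of 22 above 0 (camera, adjusted p = 8.25e-06, or adjusted p = 0.527 with an estimated correlation), with 3 members called over all genes and 5 adjusted over the list alone, and its median was 0.06 without GW1516 replicate 1. Lipid uptake and storage had a median of 0.28 (camera, adjusted p = 0.000383, or adjusted p = 0.597 with an estimated correlation), with 0 members called over all genes and 5 adjusted over the list alone, such as Slc27a1 at 1.14. Lipid synthesis had a median of 0.26 (camera, adjusted p = 0.00301, or adjusted p = 0.681 with an estimated correlation), with Lpin1 called over all genes and Lpin1 and Acacb adjusted over the list alone. It lost the threshold without GW1516 replicate 1 or 3 (medians 0.10 and 0.09). Its median on GW1516 replicate 2 was -0.43, and without that array the list stood at 0.52 (camera, adjusted p = 3.09e-09, or adjusted p = 0.135 with an estimated correlation). Adipocyte markers had a median of 0.60 (camera, adjusted p = 0.0107, or adjusted p = 0.776 with an estimated correlation), and the per-array medians of that list were 0.65, -0.20 and 1.17, beside which the lipid lists stand. It lost the threshold in 4 of 12 omissions of 1 array, where the smallest median was 0.31. Fast-twitch fibre genes had a median of 0.11 (camera, adjusted p = 0.00916, or adjusted p = 0.772 with an estimated correlation), and lost the threshold with quantile normalization (median -0.01, camera, adjusted p = 0.881) and in 2 omissions, with a median of 0.02 without GW1516 replicate 1. Adjusted over the list alone, neither of these last lists had a member called.

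The remaining GW1516 lists also stood apart on GW1516 replicate 2. All 22 atrophy and FOXO genes lay above 0, with a median of 0.60 (camera, adjusted p = 3.82e-11, or adjusted p = 0.527 with an estimated correlation), and 9 passed adjusted over the list alone, such as Foxo1 at 0.85 and Cebpb at 0.59, against 0 over all genes. The list's per-array medians were 0.17, 1.34 and 0.22. All 31 ubiquitin-proteasome genes lay above 0, with a median of 0.23 (camera, adjusted p = 1.58e-10, or adjusted p = 0.597 with an estimated correlation) and per-array medians of 0.07, 0.49 and 0.07. Fibroblast and matrix genes had a median of -0.37 with 20 of 21 below 0 (camera, adjusted p = 0.000262, or adjusted p = 0.74 with an estimated correlation), with per-array medians of -0.16, -1.11 and 0.04. Oxidative phosphorylation had a median of -0.10 (camera, adjusted p = 0.00227, or adjusted p = 0.878 with an estimated correlation), with per-array medians of 0.13, -0.28 and -0.13. The TCA cycle list had a median of -0.12 (camera, adjusted p = 0.0151, or adjusted p = 0.776 with an estimated correlation), as in Dlat at -0.26, with per-array medians of 0.09, -0.26 and -0.13. Both lost the threshold without GW1516 replicate 3 (camera, adjusted p = 0.111 and 0.185), and the TCA cycle list without vehicle replicate 1 (adjusted p = 0.111). Without GW1516 replicate 2 the matrix, oxidative phosphorylation and TCA cycle lists had adjusted p = 0.8, 0.941 and 0.635 by camera. Without it the atrophy and proteasome lists shrank to medians of 0.18 and 0.07 (camera, adjusted p = 5.45e-05 and 0.00146, or adjusted p = 0.135 with an estimated correlation for each). With fry 0 lists passed, and another grouping of the same 6 arrays put 12 lists past the threshold.

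**Figure D2:**
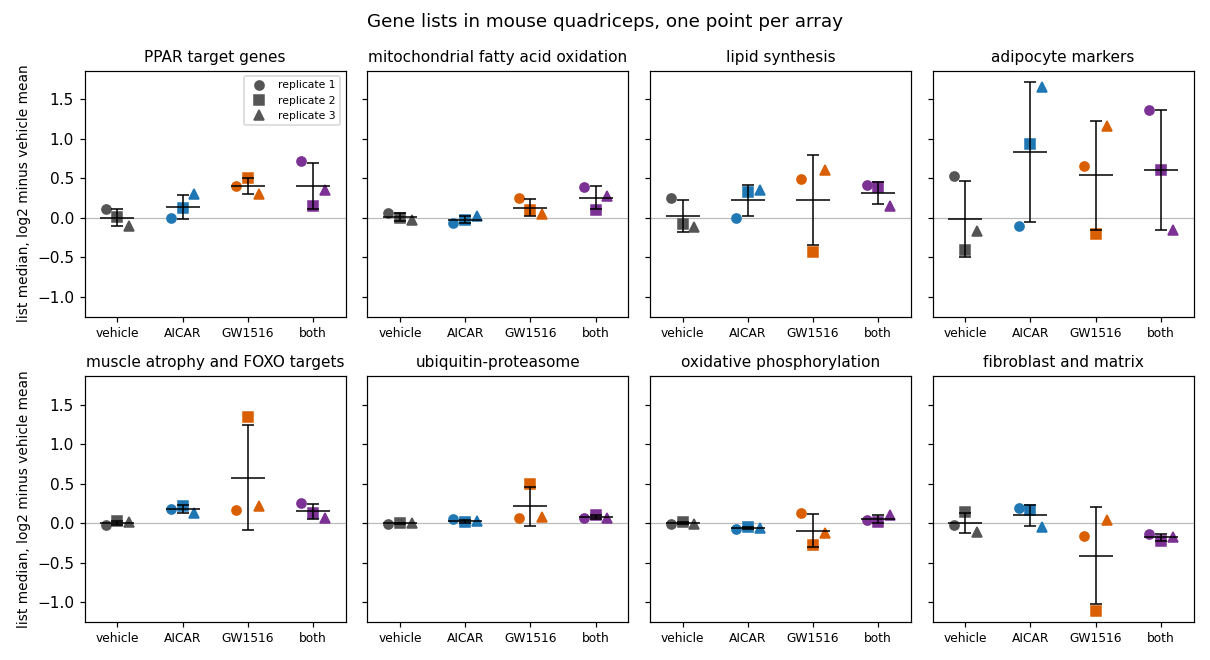
Each panel plots 1 gene list as the median over the list's measured members of log2 signal minus the vehicle mean, where points are arrays with the shape giving the replicate, and the black bar and whiskers are the mean and SD of 3 arrays. GW1516 replicate 2 lies at 1.34 for atrophy and FOXO targets and at -1.11 for fibroblast and matrix genes, and adipocyte markers range from -0.40 to 1.66 over the 12 arrays.

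The third comparison asked what both drugs did together. Foxo1 rose by 1.59 ± 0.20 (3.00-fold, n = 3 against 3 arrays), Ucp3 by 1.46 ± 0.16, Pdk4 by 1.32 ± 0.24 and Fbp2 by 1.31 ± 0.13, with limma's adjusted p = 0.00405, 0.000996, 0.0466 and 0.000432. Sult1a1 rose by 1.14 ± 0.16, the fatty acid transporter gene Slc27a1 by 1.10 ± 0.21, Acadl by 0.99 ± 0.11 and Mlycd by 0.97 ± 0.18, with adjusted p = 0.0088, 0.0477, 0.00127 and 0.0467. Pfkfb3 fell by 2.28 ± 0.22 (4.87-fold lower, adjusted p = 0.000432). The clock repressors Nr1d1 and Bhlhe40 fell by 0.94 ± 0.16 and 0.81 ± 0.15 (adjusted p = 0.0346 and 0.0451). In each of these genes all 3 combination arrays lay on 1 side of the 3 vehicle arrays.

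Of 33 genes called, 20 rose and 13 fell, and 1387 genes had an unadjusted p under 0.05, where 639 would fall by chance. Arap1 at -1.28, Dhx36 at -0.98, Sh3bp5 at -0.94, Dkk3 at -0.86 and the non-coding gene Airn at -0.73 were also among the largest falls. Other probe sets of Dhx36, Sh3bp5 and Airn reached -0.02, 0.00 and 0.83. Angptl4 differed by 1.62 and missed the threshold (limma, adjusted p = 0.097), and Fasn at 1.04, Scd1 at 0.75, Myh4 at 0.28, Prkaa2 at 0.20, Ppard at 0.04 and Ppargc1a at -0.04 did not pass, with Fasn at 0.55 without combination replicate 1. The count was 10 without vehicle replicate 1 or 2, 18 without vehicle replicate 3, 12 and 14 without combination replicates 2 and 3, 19, 13 and 18 without AICAR replicates 1, 2 and 3, and 95 without GW1516 replicate 2. With 1 array left out in turn, Pfkfb3, Fbp2, Ucp3, Foxo1, Plin4, Acadl and Sult1a1 were called in 12 of 12 fits, Nr1d1 in 5, and Pdk4, Mlycd and Bhlhe40 in 3. The count was 18 with no filter on dim probe sets, 92 with array weights and 2 without the trend.

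For the combination, 8 lists passed camera, 7 higher and 1 lower. PPAR target genes had a median of 0.47 with 22 of 23 members above 0 (camera, adjusted p = 1.92e-11, or adjusted p = 0.264 with an estimated correlation). Over all genes 5 members were called, Mlycd, Pdk4, Plin4 at 0.88, Slc25a20 at 0.76 and Ucp3, and 9 when adjusted over the list alone. Mitochondrial fatty acid oxidation had a median of 0.23 with 21 of 22 above 0 (camera, adjusted p = 5.08e-09, or adjusted p = 0.264 with an estimated correlation), with 4 members called over all genes, such as Crat at 0.41, and 8 adjusted over the list alone. Fry, which asks whether a list's genes move 1 way on balance, also called both lists (adjusted p = 0.0207 for each). These lists share members such as Mlycd and Slc25a20, so their results are not separate. Fry called the circadian clock list as well (adjusted p = 0.0342), which camera did not call. Lipid uptake and storage had all 17 members above 0 and a median of 0.42 (camera, adjusted p = 8.95e-06, or adjusted p = 0.35 with an estimated correlation), with Slc27a1 called over all genes and 3 members adjusted over the list alone. Lipid synthesis had a median of 0.40 (camera, adjusted p = 0.000129, or adjusted p = 0.426 with an estimated correlation), with 0 members called over all genes and 3 adjusted over the list alone, among them Lpin1 at 0.40.

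All 17 fast-twitch fibre genes lay above 0 with a median of 0.20 (camera, adjusted p = 5.82e-05, or adjusted p = 0.502 with an estimated correlation), as in Atp2a1 at 0.25 and Tnnc2 at 0.24. The atrophy and FOXO list had a median of 0.22 (camera, adjusted p = 0.0193, or adjusted p = 0.745 with an estimated correlation), with Foxo1 and Pdk4 called over all genes and 3 members adjusted over the list alone. Adipocyte markers had a median of 0.65 (camera, adjusted p = 0.042, or adjusted p = 0.745 with an estimated correlation) and per-array medians of 1.37, 0.61 and -0.15. Adipocyte markers lost the threshold in 6 of 12 omissions, where the smallest median was 0.22, and with quantile normalization, median centring or no filter. The atrophy and FOXO list lost it in 2 omissions, and the fast-twitch list with quantile normalization (median 0.04, camera, adjusted p = 0.472). Without combination replicate 1 the PPAR and lipid uptake lists had medians of 0.30 and 0.20 and passed. Immediate early and heat shock genes had a median of -0.23 with 17 of 20 below 0 (camera, adjusted p = 0.00273, or adjusted p = 0.35 with an estimated correlation). Junb at -1.64, Ier2 at -0.75 and Dnajb1 at -0.54 passed adjusted over the list alone, and 0 members passed over all genes. Junb stood at -2.51, -0.27 and -2.13 on the combination arrays, with -0.27 inside the vehicle range of -0.63 to 0.72. Another grouping of the same 6 arrays put 9 lists past the threshold.

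Set against AICAR alone, the combination had higher levels of 4 genes. Fbp2 was higher by 1.20 ± 0.13, Ucp3 by 1.04 ± 0.16, the carnitine carrier gene Slc25a20 by 0.84 ± 0.11 and Acadl by 0.75 ± 0.11, with limma's adjusted p = 0.00217, 0.0461, 0.0229 and 0.0461. No other gene was called, and 935 genes had an unadjusted p under 0.05. Next in rank without passing were Gins3 at 1.41 on the higher side and Cnih2 at -2.46, Htra4 at -1.15, Mss51 at -0.96, Nlrx1 at -0.59 and Pfkfb3 at -1.01 on the lower. Leaving out any 1 AICAR, combination or vehicle array left 1 or 2 genes, and leaving out GW1516 replicate 2 gave 10. Fbp2 was called in 12 of these 12 fits, Slc25a20 in 6, and Ucp3 and Acadl in 3. The count was 2 with quantile normalization and 2 without the dim filter.

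Between the combination and AICAR 7 lists passed camera, 6 higher in the combination. Mitochondrial fatty acid oxidation had a median of 0.20 (camera, adjusted p = 8.91e-13, or adjusted p = 0.211 with an estimated correlation), with 2 members called over all genes and 11 adjusted over the list alone, such as Etfb at 0.48. Fry called this list as well (adjusted p = 0.029). PPAR target genes had a median of 0.36 (camera, adjusted p = 7.96e-10, or adjusted p = 0.27 with an estimated correlation), with 2 members called over all genes and 12 adjusted over the list alone, such as Fabp3 at 0.55 and Mlycd at 0.91. Oxidative phosphorylation, fast-twitch fibre, ribosomal protein and TCA cycle genes had medians of 0.11, 0.11, 0.06 and 0.07 (camera, adjusted p = 5.58e-07, 0.0106, 0.0202 and 0.033, or adjusted p = 0.763 with an estimated correlation for each). Fibroblast and matrix genes had a median of -0.27 (camera, adjusted p = 0.0106, or adjusted p = 0.763 with an estimated correlation). In these 5 lists 0 members passed, over all genes or adjusted over the list alone. With quantile normalization 3 of the 7 lists passed, and the TCA cycle, matrix and ribosomal lists each lost the threshold in 2 of 12 omissions.

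Between the combination and GW1516 alone, 0 genes passed by limma (smallest adjusted p = 0.193), with 1326 at an unadjusted p under 0.05, and 1 gene passed without the trend. The leading values were Pfkfb3 at -1.32 ± 0.22 and Luc7l3 at -0.61 ± 0.11 on the lower side, and Ifngr2 at 0.82 ± 0.14 and Vapb at 1.01 ± 0.18 on the higher, where other probe sets of Luc7l3 and Ifngr2 reached 0.42 and -0.04. Without GW1516 replicate 1 the count was 10 and without GW1516 replicate 3 it was 2. Camera put 4 lists past the threshold: oxidative phosphorylation at 0.13 and TCA cycle at 0.13, and atrophy and FOXO targets at -0.33 and ubiquitin-proteasome at -0.17 as medians (adjusted p = 3.9e-06, 0.00398, 0.00109 and 6.87e-06, or adjusted p = 0.838 with an estimated correlation for each). Of their members 0 passed, over all genes or adjusted over the list alone, and the number of lists was 0 without GW1516 replicate 2 and 7 without GW1516 replicate 1 or 3.

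Between AICAR and GW1516, 0 genes passed by limma (smallest adjusted p = 0.118), with 1168 at an unadjusted p under 0.05, 2 called with a pseudocount of 32 and 2 with array weights. The leading values, AICAR minus GW1516, included on the lower side Fbp2 at -0.85 ± 0.13, Mlycd at -1.10 ± 0.18, Acadl at -0.68 ± 0.11, Ucp3 at -0.93 ± 0.16 and Slc25a20 at -0.63 ± 0.11. On the higher side Col22a1 stood at 0.71, Agbl5 at 1.12, Dync1i2 at 0.85, Nmnat2 at 1.43 and Runx1 at 1.87. Without GW1516 replicate 1 the count was 1, and without GW1516 replicate 2 it was 2. Of 7 lists past the threshold, PPAR targets had a median of -0.35 and fatty acid oxidation of -0.14 (camera, adjusted p = 8.56e-08 and 4.51e-07, or adjusted p = 0.381 with an estimated correlation for each). They had 10 and 8 members lower when adjusted over the list alone and 0 over all genes, and in the other lists only Cavin4 and Pdk4, of the atrophy list, passed adjusted over the list alone. Ribosomal protein genes had a median of -0.11 (camera, adjusted p = 3.01e-05, or adjusted p = 0.381 with an estimated correlation). Their median was -0.07 without GW1516 replicate 1, and that of PPAR targets was -0.23 without AICAR replicate 1. Both lists passed in every omission of 1 array. The ubiquitin-proteasome, atrophy and FOXO, matrix, and macrophage and immune cell lists had medians of -0.19, -0.43, 0.54 and 0.40 (camera, adjusted p = 2.74e-08, 6.63e-06, 6.63e-06 and 0.00207, or adjusted p = 0.757 with an estimated correlation for each). These 4 were lost without GW1516 replicate 2, at adjusted p = 0.0856, 0.71, 0.0541 and 0.0813 by camera.

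The last comparison asked whether the combination differed from the sum of both single-drug changes. By limma 0 genes passed (smallest adjusted p = 0.703), 848 had an unadjusted p under 0.05, and 0 passed under each alternative that kept the adjusted threshold. The median standard error of this contrast was 0.27. Leading values were Polh at 1.08, Cntfr at 1.83, Vapb at 1.20, Ndufaf1 at 0.61 and Neu2 at 0.72 above the sum, and Exosc5 at -0.69, Lpin1 at -0.56, Cnih2 at -3.46, Ces1h at -3.44 and Nudt18 at -0.86 below it. Camera put 5 lists past the threshold, oxidative phosphorylation and TCA cycle genes above the sum by a median of 0.20 and 0.18, and atrophy and FOXO targets, adipocyte markers and proteasome genes below it at -0.43, -0.92 and -0.19. For each of them adjusted p = 0.946 with an estimated correlation. Adipocyte markers lost the threshold in 5 of 12 omissions and the proteasome list in 1. Without GW1516 replicate 2 the oxidative phosphorylation, TCA cycle and atrophy lists shrank to medians of 0.11, 0.11 and -0.18. They still passed there (camera, adjusted p = 0.000179, 0.0169 and 0.0169). None of the members of these 5 lists passed over all genes or adjusted over the list alone, and 82 of 100 drawn groupings of the 12 arrays put as many lists past the threshold.

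The single-drug responses shared 0 called genes, where at most 1 was possible, since AICAR had 1 called gene. That gene, Rpl22l1, was also lower with GW1516, without passing. The single-drug log2 changes correlated across genes with r = 0.457, where 100 simulations of unchanged groups sharing the vehicle arrays gave 0.50, and genes are not independent replicates. The covariance was 0.0536 against 0.0534 in the simulations. GW1516 and the combination shared 8 called genes, Acadl, Fbp2, Mlycd, Plin4, Ptp4a3, Tacc2 and Ucp3 higher and Dkk3 lower. Both comparisons use the same vehicle arrays, and 20 simulations of unchanged groups shared 0 genes, with 0 called for GW1516 in any of them. Without GW1516 calls those simulations had to share 0, so they cannot judge the overlap of 8. The correlation was 0.470 against 0.499 simulated (SD 0.0136), and the covariance 0.0607 against 0.0534. AICAR and the combination shared Rpl22l1, with a correlation of 0.540 against 0.497 simulated and a covariance of 0.0707 against 0.0531. Sharing as such is already in the simulated values. On the same vehicle arrays, the covariance of AICAR with GW1516 exceeded the simulated value by 0.00019 (SD over simulations 0.0019). The shared vehicle arrays are too few to split, so a part from them in the excess of the other pairs is not excluded. With 3 arrays a group, 10% of genes would separate 2 groups fully by chance; 18.3% did for AICAR, 14.2% for GW1516 and 18.6% for the combination against vehicle.

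The gene lists that camera did not call against vehicle had medians between -0.19 and 0.23 for AICAR (20 lists, smallest adjusted p = 0.0515), between -0.23 and 0.07 for GW1516 (15 lists, smallest adjusted p = 0.107) and between -0.31 and 0.33 for the combination (18 lists, smallest adjusted p = 0.117). Among them in all 3 comparisons were peroxisome, cholesterol synthesis, glycolysis and glycogen, slow-twitch fibre, metabolic regulator, angiogenic factor, endothelial, macrophage and immune cell, satellite cell, nerve and Schwann cell, circadian clock, integrated stress response and interferon response genes. Within glycolysis Pfkfb3 fell with the combination, and within the clock list Nr1d1 and Bhlhe40 did, joined by Ciart when adjusted over the list alone. For AICAR the smallest adjusted p, 0.0515 by camera, was that of the atrophy and FOXO list. Without GW1516 replicate 2 that list and PPAR targets passed for AICAR (camera, adjusted p = 0.00108 and 0.0437). With an estimated correlation they did not pass there either (camera, adjusted p = 0.518 and 0.726).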

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

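The tests on GW1516 replicate 2 and on fat cells were chosen only after the results were seen, while the counts over other splits of the arrays were planned.

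These 5 gene lists drew attention because the response to the combination differed from the sum of both drugs by a test of that difference. Camera's adjusted p was 4.15e-09 for oxidative phosphorylation, 0.000508 for the TCA cycle, 1.02e-05 for atrophy and FOXO targets, 0.00569 for adipocyte markers and 5.03e-05 for the proteasome. With an estimated correlation each had an adjusted p of 0.946, and without GW1516 replicate 2 the proteasome list had 0.172. Chance cannot be excluded for these lists: 82 of 100 drawn splits of the 12 arrays gave as many, with 5 in the real split and 13 in the highest other. For single genes the interaction gave 0 by limma, with 848 at an unadjusted p under 0.05, and since no split can give fewer than 0, its 100 of 100 splits (highest other 1) say nothing about chance.

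Some probe sets that carry no gene name here, which the gene comparisons do not use, also passed. With all 27022 probe sets tested by limma, 2 of the 3686 unnamed passed for AICAR, both higher, and 10 for the combination, 5 higher and 5 lower, with 0 for GW1516. Over all 27022 probe sets, 3 passed for AICAR, 79 for the combination and 11 for GW1516. With the combination the unnamed thus passed at about the same share as all probe sets.

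GW1516 replicate 2 stood apart, with a median of 1.34 for atrophy and FOXO genes against 0.17 and 0.22 on the other GW1516 arrays. RNA degradation is argued against by its Gapdh 3' to 5' ratio of 0.863, inside the range of the other 11 arrays, 0.802 to 0.880, and by 0.839 for Actb, inside 0.782 to 0.936. Array scaling is argued against by a median of 1.33 after quantile normalization. A lower share of all non-muscle cells would lower their markers alike, but endothelial markers lay 1.04 above matrix markers, at -0.07 (quartiles -0.23 and 0.01) against -1.11 (quartiles -1.39 and -0.78). Macrophage and immune cell markers were lower too, at -0.54 (quartiles -0.79 and -0.11), so a lower share of some of these cells is not excluded. A different physiological state of the pooled mice may account for it and stays open, since no label records such a state. On this array 20 of 22 atrophy and FOXO genes, such as Fbxo32 at 2.65 and Trim63 at 2.25, were highest. That count restates the pattern in the same genes, so it cannot bear on the cause.

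Fat cells in the pools may account for part of the higher lipid genes, since the adipocyte marker score, the mean log2 signal of Adipoq, Retn, Cidec and Fabp4, ranged from -0.53 to 1.70 around the vehicle mean, and Adipoq from 660 to 4385 and Fabp4 from 3699 to 11534 in signal. With the score in the model, the lipid synthesis list without members shared with the adipocyte list went for GW1516 from a median of 0.25 (SD of members 0.23) to -0.02 (SD 0.30), with camera's adjusted p going from 0.00279 to 0.352, as fat cells would give. On GW1516 replicate 2, however, the score was 0.162 while the full lipid synthesis list had a median of -0.427. On replicates 1 and 3 the scores were 0.565 and 1.241, with medians of 0.495 and 0.609. The score model was not run without replicate 2, so the weight of that array in the GW1516 result is not known. For AICAR the list without shared members missed the threshold even without the score (adjusted p 0.0752, then 0.768), so the explanations cannot be told apart there. Lipid uptake and storage, for which no prediction was written, went with the score from 0.28 to 0.17 for AICAR (adjusted p 0.00207, then 0.454) and from 0.28 to 0.12 for GW1516 (0.000383, then 0.0335), which leaves fat cells open there. For the combination lipid uptake and storage went from 0.42 to 0.28 and stayed past the threshold (8.95e-06, then 0.000404), which argues against fat cells as the whole cause there by the measure used for the other lists. Lipid synthesis without the shared members kept, for the combination, a median of 0.23 of 0.30 (adjusted p 0.0105), and PPAR targets went from 0.41 to 0.36 for GW1516 (adjusted p 3.8e-08) and from 0.47 to 0.28 for the combination (3.06e-08), past the threshold of camera at its preset correlation, which argues against fat cells as the whole cause. With an estimated correlation these PPAR lists did not pass even without the score (adjusted p 0.343 and 0.264), and the full list of 18 lipid synthesis genes with the combination did not either (0.426). Lipid uptake and storage with the combination did not pass that way either. Some score genes are PPAR targets themselves, so the score can also remove a drug effect.

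Across the 12 arrays the score and the median of those 15 lipid synthesis genes correlated with Pearson's r = 0.622 (permutation p = 0.034) and Spearman's rho = 0.531 (permutation p = 0.082), the 1 relation computed. Without AICAR replicate 3 and vehicle replicate 2, the farthest from the median, r was 0.625, and within groups it was 0.629.

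Other splits of the same arrays gave these counts. Chance is unlikely for the F test, where 1 of 100 drawn splits, the real one with 14 genes, gave as many and the highest other gave 2. It is not excluded, since 1 of 100 is the smallest share these draws can give. The draws also treat the pools as independent, which the labels do not settle. For comparisons of 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split and the highest other gave 1 and 0 genes for AICAR, 12 and 1 for GW1516, 33 and 1 for the combination, and 4 and 0 for the combination against AICAR, so 1 of 10 splits, the real one, reached each count. They gave 0 and 3 for the combination against GW1516 and 0 and 0 for AICAR against GW1516, where all 10 reached it, as any split must when the count is 0. For lists, the real split and the highest other gave 6 and 7 for AICAR, 11 and 12 for GW1516, 8 and 9 for the combination, 7 and 8 for the combination against AICAR, 4 and 9 for the combination against GW1516, and 7 and 10 for AICAR against GW1516. The splits reaching these list counts numbered 2, 2, 3, 2, 10 and 9 of 10.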

How the results depend on the processing

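The adipocyte marker score as covariate was chosen only after the data were seen, and the other alternatives were planned. Alternatives other than leaving out arrays, planned and added, kept named genes on their side of the threshold in 2764 cases. The threshold was lost in 89 cases and gained in 37. A change of sign in a gene called in neither fit was counted as kept. With 1 array left out the numbers were 2973, 159 and 36. Most of the kept cases were named genes not called in the main fit, which had no call to lose. All the losses fell on the fewer called genes, so calls were less stable than these totals. Pdk4 with the combination kept its call in 4 of 11 alternatives and 3 of 12 omissions. Fbp2 and Pfkfb3 with the combination, and Fbp2 between the combination and AICAR, were called under all 11 alternatives and all 12 omissions; Ucp3, Plin4, Acadl, Foxo1 and Sult1a1 with the combination were called in 12 omissions and 10 of 11 alternatives. Counts of called genes moved by over 1.5 times as follows. For AICAR the count of 1 became 4 with quantile normalization, a pseudocount of 32, a 60% filter, robust variances, an adjusted p below 0.10 or the replicate block, 3 with all probe sets, 0 without trend, 28 with only the groups compared, 370 at an unadjusted p under 0.05 and 1.5-fold, 15 with array weights and 0 with the score, and 0 to 8 with an array left out. For GW1516 the count of 12 became 7 with the mean of probe sets, 0 without trend, 2 with only the groups compared and 332 at the unadjusted threshold, and 0 to 41 with an array left out. For the combination the count of 33 became 18 without filter, 79 with all probe sets, 2 without trend, 75 below 0.10, 519 at the unadjusted threshold, 92 with array weights, 16 with the replicate block and 19 with the score, and 10 to 95 with an array left out. Between the combination and AICAR the count of 4 became 2 with quantile normalization, no filter, the mean of probe sets or the score, 1 with all probe sets or the replicate block and 330 at the unadjusted threshold, and 1 to 10 with an array left out. Between the combination and GW1516 the count of 0 became 1 without trend and 448 at the unadjusted threshold, and 0 to 10 with an array left out. Between AICAR and GW1516 the count of 0 became 1 with median centring, 2 with a pseudocount of 32 or array weights and 418 at the unadjusted threshold, and 0 to 2 with an array left out. For the interaction the count of 0 became 436 at the unadjusted threshold and stayed 0 with any array left out. The F test's 14 became 25 with all probe sets, 0 without trend, 24 below 0.10 and 45 with array weights, and 7 to 38 with an array left out. The overlap of 0 between AICAR and GW1516 became 1 with quantile normalization, a pseudocount of 32, a 60% filter, an adjusted p below 0.10 or the replicate block, and 0 to 3 with an array left out. With an estimated correlation 0 lists passed in each comparison; fry called 3 for the combination, 1 between the combination and AICAR and 0 in the others. The score left 3 of 6 lists for AICAR, and quantile normalization 3 of 7 between the combination and AICAR. With an array left out the lists numbered 4 to 8 for AICAR, 8 to 11 for GW1516, 6 to 9 for the combination, 5 to 9 between the combination and AICAR, 0 to 7 between the combination and GW1516 (0 without GW1516 replicate 2, 7 without GW1516 replicate 1 or 3), 6 to 9 between AICAR and GW1516 and 4 to 6 for the interaction. Reversed directions of the list test, read only for lists past the threshold in at least 1 of the fits compared, were the adipocyte list with the score, at -0.0363 for AICAR, -0.0541 for GW1516, -0.0209 for the combination and 0.0345 for the interaction, by construction, since the score is made from its members. Among lists past the threshold with or without GW1516 replicate 2, leaving it out reversed the direction of camera's test in 4. The median of oxidative phosphorylation with GW1516 went to -0.00537 (range over omissions -0.215 to -0.00537) and between AICAR and GW1516 to -0.0574 (range -0.0574 to 0.123). Atrophy and FOXO targets between the combination and GW1516 went to -0.0389 (range -0.535 to -0.0389), and matrix genes in the interaction to -0.222 (range -0.222 to 0.281). The fast-twitch list between the combination and AICAR reversed in its test with quantile normalization (median 0.0142). Among lists past the threshold in at least 1 of the fits, the median alone changed sign, with the direction of the test kept, for lipid synthesis with the score (-0.00193 for AICAR and -0.0933 for GW1516) and between AICAR and GW1516 without GW1516 replicate 2 (from 0.12 to -0.123), for the fast-twitch list with GW1516 (-0.00690) and ribosomal proteins between the combination and AICAR (-0.0141) with quantile normalization, and for the slow-twitch list between the combination and AICAR without combination replicate 2 (0.248). Without trend the prior degrees of freedom were 1.95 in place of 5.91, thresholds differ by construction, and for the other changes the cause was not tested. Arrays of the same replicate number did not deviate together (mean r -0.0142 over 18 pairs, 0 over 0.1, and 2 arrays closest to their own number), so the samples were not paired, and the replicate block changed the other gene and list counts by less than 1.5 times. Dim probe sets limit what can be seen: a signal of 28.2 was the filter's threshold.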

Other observations

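Nothing in this part was tested beyond the planned comparisons, and no test was added after the results were seen.

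With the combination, circadian genes went both ways. Nr1d1 and Bhlhe40 fell by 0.94 and 0.81 on the log2 scale (limma, adjusted p = 0.0346 and 0.0451), and Ciart stood at -0.78, Bhlhe41 at -0.51 (-1.20, -0.19 and -0.13 by array), Clock at -0.48 and Dbp at -0.20 without passing over all genes, while Tef stood at 0.07, Per2 at 0.44 and Arntl at 0.28, none of them passing. The list's median was -0.02 with 9 of 16 members below 0 (camera, adjusted p = 0.18, and fry, adjusted p = 0.0342). With AICAR alone Nr1d1 and Bhlhe40 passed adjusted over the list alone and not over all genes.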
